A study of Homo sapiens with 4 samples.

How the data were processed

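The series holds 4 libraries of ACHN, a human renal cell carcinoma line, all labelled with 4-thiouridine (S4U), a uridine analogue that cells build into RNA during the labelling time. The labels give 2 libraries as wild type for ZCCHC8 and 2 as knockout of ZCCHC8, named control and knockout here. Per the labels' protocols, total RNA was treated with iodoacetamide, which alkylates the incorporated analogue so that it is read as T-to-C conversions (SLAM-seq), and ribosomal RNA was removed before library construction. The labelling time, the number of clones behind the knockout libraries and whether replicates were separate cultures are not given in the sources used here. The p-values of single features therefore measure only the spread between these 4 samples. Those of gene lists, lncRNA classes and Gene Ontology terms set features against other features of the same comparison. Loci or genes that overlap can share reads, so they are not independent there.

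The authors deposited 4 tables, of all reads over coding genes, converted reads over coding genes, all reads over lncRNA loci and converted reads over lncRNA loci. Per the file headers, each table holds a read count per library, and the values were whole numbers. Per the file headers, each table also holds CPM, and division of counts by CPM showed that the authors scaled all 4 tables of a library to one read total, of 74.59 and 70.52 M in the controls and 78.64 and 80.83 M in the knockouts. The authors' CPM of converted reads is therefore relative to all reads of the library and not to its converted reads. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.3, checked with FastQC and handled on the human build hg19, on which all coordinates below stand. The aligner, counting program, strand setting, annotation version and rule for calling a read converted are not given in the sources used here. All 13596 features listed in both the lncRNA and the gene table had identical read numbers in all 4 libraries, so these tables are not independent. Of the 42059 lncRNA loci, 27462 overlapped the span of a coding gene and 14597 did not. Over loci nested in deeply read genes, read density in all reads was 1.02 times that of the host on the same strand and 0.987 times on the opposite strand. In converted reads these ratios were 1.23 and 0.106, so all reads were counted without regard to strand at such loci while converted reads were mostly resolved by strand.

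Total reads per library ran from 30.02 to 33.98 M over genes and from 38.31 to 43.15 M over lncRNA loci. Converted reads ran from 6.789 to 7.371 M over genes and from 7.409 to 7.978 M over lncRNA loci. The labels name no molecular identifiers, so counting precision is an upper limit on how well a level is known.

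Each table was tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood fit and test, 2 knockout against 2 control libraries). Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over all tested features. Levels are printed as TMM-scaled CPM of the tested reads, and changes as log2 knockout over control with the standard error of the fit. TMM puts the typical gene at no change, whereas the authors' CPM places the median newly made mRNA at -0.245 and the median newly made lncRNA locus at -0.223 on the log2 scale, so all changes in newly made RNA are relative to the typical newly made RNA. The medians by the authors' CPM were -0.0199 for all reads over genes and -0.0077 over lncRNA loci.

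The newly made share of a feature, converted reads over all reads, was tested with limma 3.58.1 on log2 ratios with a pseudocount of 0.5, for features with at least 10 reads in both tables in 2 libraries, centred on each library's median. A variance trend on total reads was made part of this test after the data were seen, because on simulated lncRNA data the fit without it recovered 0% of 2-fold changes of 200 features, against 55% with it. For mRNA the figures were 66.5% and 75%. Converted reads were drawn there with counting noise alone, without further variation between replicates. Real converted reads over lncRNA loci varied more, at 1.51 times counting noise between controls and 1.45 times between knockouts. The simulation therefore does not show how many calls with the trend are right in the real libraries.

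Gene groups were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the data, for lists with at least 5 tested members. The 26 lists covered the NEXT complex, the nuclear exosome, PAXT and other exosome adaptors, snoRNA host genes, abundant nuclear lncRNAs, replication-dependent histones, PRC2 and H3K27 demethylases, Polycomb-marked developmental genes, Polycomb-silenced tumour suppressors, semaphorins and axon guidance, immediate early genes, p53 targets, interferon-stimulated genes, the integrated stress and unfolded protein response, heat shock proteins, cell cycle, DNA repair, hypoxia response, epithelial markers, mesenchymal and matrix genes, renal tubule genes, immune cell markers, endothelial markers, mitochondrially encoded mRNAs, ribosomal proteins, and C2H2 zinc finger and short-lived regulators. They held 814 symbols, of which 791 were found. Apart from the variance trend, the tests, lists, most alternatives and the rule for named features were fixed before the data were examined. That rule takes ZCCHC8 and then, per table, the 8 features with the largest rise and the 8 with the largest fall among called features in the upper part of the level range (above the median of tested features) whose knockout libraries both lie beyond both controls, and for each list the members with the smallest p. Not every feature so chosen is printed. Applying the same rule to lncRNA loci that overlap no coding gene, and to bidirectional loci, was decided after the data were seen. The axon guidance list was written with SEMA5A in mind from knowledge of the study, so it is not independent evidence.

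The lncRNA classes of the deposited annotation and locus length were tested by the difference of median log2 changes with and without the property, with 10000 two-sided permutations within strata of 5 length and 3 level classes. G-quadruplex motifs and U content, which the series title names, and exon number were not tested, because neither sequence of this build nor exon structure was at hand. Spearman correlations across features describe how changes in all reads and in converted reads compare, and features are not independent replicates.

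Gene Ontology terms of 10 to 300 tested genes were examined with a one-sided hypergeometric test, after the data were seen. The calls were tested on simulated data with the real libraries' means and sizes and 200 changed features. For all reads over genes, 92% of 2-fold and 51% of 1.2-fold changes were recovered, and 5.49% of calls were unchanged genes. Of 2-fold changes, 83.3% were recovered for newly made mRNA, 85.7% for lncRNA loci and 64% for newly made lncRNA loci, with 6.96%, 5.81% and 5.17% of calls unchanged features. Alternatives tried were DESeq2 1.42.0 and its size factors, no filter and a minimum of 50 reads in 2 libraries, replicate number as a block, a 2-fold minimum, limma on log2(CPM + 1) of the authors' values, each library left out in turn, an estimated inter-gene correlation and, added after the data were seen, fits without chromosome 7 and fits restricted to loci that overlap no coding gene. Further work used the package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.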

Results

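The data described the RNA of ACHN cells, a human renal cell carcinoma line, with and without knockout of ZCCHC8. ZCCHC8 is the scaffold of the NEXT complex, which hands short-lived nuclear transcripts to the RNA exosome. The series title asks how this complex acts on lncRNAs, H3K27me3 and cancer progression. Each of 2 control and 2 knockout libraries was read as all RNA and as newly made RNA, the latter being reads with T-to-C conversions from an S4U label. Control replicates 1 and 2 held 31.59 and 30.02 M reads over genes, and knockout replicates 1 and 2 held 33.27 and 33.98 M. In the same order, converted reads over genes were 7.371, 7.272, 6.789 and 7.065 M. Over lncRNA loci the libraries held 40.46, 38.31, 42.19 and 43.15 M reads, of which 7.978, 7.869, 7.409 and 7.715 M carried conversions. All changes below are log2 ratios of knockout over control with the standard error of the edgeR fit, n = 2 libraries per group, and levels are TMM-scaled CPM.

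ZCCHC8 (ENSG00000033030; hg19 chromosome 12, 122957417 to 122985518) was at 94.3 and 94.0 CPM in the controls and at 47.0 and 46.9 in the knockouts. Its RNA fell by 1.00 ± 0.0369 on the log2 scale (edgeR adjusted p = 4.49e-21), so transcript remained at a 2.00-fold lower level. Newly made ZCCHC8 RNA was at 145 and 142 in the controls against 95.2 and 96.2 in the knockouts, a log2 change of -0.58 ± 0.0579 (adjusted p = 1.92e-10). The labelled groups and this gene went the same way in every library, while the RNA level says nothing of the protein. Of the 3 NEXT complex genes 1 rose and 1 fell, the same counts adjusted over the list alone: RBM7 rose by 0.19 ± 0.0492 and the helicase SKIV2L2 stood at -0.03 ± 0.0335 (adjusted p = 0.48). Across the nuclear exosome, 4 of 14 genes rose and 0 fell (edgeR), with EXOSC6 at 0.28 ± 0.0621, EXOSC4 at 0.31 ± 0.125, EXOSC3 at 0.13 ± 0.0466 and EXOSC7 at 0.12 ± 0.0469. Adjusted over the list alone, 1 rose and 0 fell. Among 17 PAXT and other exosome adaptor genes, 2 rose and 2 fell (the same counts adjusted over the list alone), with SRRT (chromosome 7) at 0.33 ± 0.0322 and C17orf85 at -0.23 ± 0.0367. Newly made SRRT RNA was at -0.33 ± 0.0892, near the median of chromosome 7 given below. Camera called neither of these lists, with adjusted p = 0.866 for both.

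In all RNA over coding genes, the knockout cells held far more message for a prostacyclin enzyme and adhesion proteins and far less for a D-type cyclin. PTGIS (chromosome 20, 48120411 to 48184683), prostacyclin synthase, rose 15.4-fold from 16.7 ± 0.668 to 256 ± 2.99 CPM (SD, n = 2), a log2 change of 3.94 ± 0.0416 (edgeR adjusted p = 1.95e-36). SEMA5A (chromosome 5, 9035138 to 9546187), a semaphorin, rose 7.39-fold from 35.2 to 260. CCND2 (chromosome 12, 4382938 to 4414516), cyclin D2, was 7.75-fold lower, at 34.4 ± 0.484 against 267 ± 5.14 in the controls. SCIN (chromosome 7, 12610203 to 12693228), an actin-severing protein, was 7.25-fold lower, at 14.6 against 106. PCDH20, a protocadherin, rose 9.62-fold, CDH13, a cadherin, 5.70-fold to 343, and PTPRM, a receptor tyrosine phosphatase, 5.03-fold to 467. ZBED2 and CD96 rose 8.59-fold and 5.97-fold, but the span of ZBED2 lies within that of CD96. Genes that fell included SLC17A1, a renal phosphate transporter, at 3.60-fold lower, LAMA1, a laminin chain, at 3.43-fold lower, and SLIT2, a guidance ligand, at 2.72-fold lower. PALM2 stood at -1.40 ± 0.0538, GPM6A at -1.27 ± 0.0612 and STRIP2 (chromosome 7) at -1.24 ± 0.0429.

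Matrix and growth-response genes moved as groups. Of 29 mesenchymal and matrix genes, 19 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 4.42e-20, and adjusted p = 0.196 with an estimated correlation). FN1, fibronectin, rose by 1.92 ± 0.0290, from 2191 to 8301 CPM, SPARC by 1.17 ± 0.0299 from 152 to 342, COL4A1 by 0.67 ± 0.0289 and THBS1 by 0.62 ± 0.0278. Of 35 immediate early genes, 25 rose and 4 fell, and 26 rose and 4 fell adjusted over the list alone (camera adjusted p = 5.53e-09, and adjusted p = 0.215 with an estimated correlation). Among them SGK1 rose by 1.15 ± 0.0417, from 32.4 to 71.8, CTGF by 0.68 ± 0.0323, RHOB by 0.61 ± 0.0369 and DUSP1 by 0.55 ± 0.0312.

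Stress-linked and mitochondrial groups went down. Of 26 p53 targets, 18 fell and 2 rose, the same counts adjusted over the list alone (camera adjusted p = 6.33e-05, and adjusted p = 0.328 with an estimated correlation). GDF15 stood at -0.69 ± 0.0400, CDKN1A, the p21 inhibitor of cyclin-dependent kinases, at -0.52 ± 0.0310 with 195 against 136 CPM, SESN2 at -0.72 ± 0.0442 and MDM2 at -0.27 ± 0.0281. Of 29 genes of the integrated stress and unfolded protein response, 13 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000238, and adjusted p = 0.435 with an estimated correlation). DDIT4, which restrains mTOR, was at -0.95 ± 0.0347 and PSAT1, of serine synthesis, at -0.32 ± 0.0329. ASNS and PDIA4, at -0.78 ± 0.0406 and -0.43 ± 0.0295, lie on chromosome 7. All 13 mitochondrially encoded mRNAs fell, likewise adjusted over the list alone, with a median of -0.229 (camera adjusted p = 0.000143, and adjusted p = 0.797 with an estimated correlation). MT-CO3 was at -0.39 ± 0.0269, from 6142 to 4695, and MT-CO2 at -0.36 ± 0.0276.

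The other lists were not called in all RNA, with camera adjusted p from 0.182 to 0.866. PRC2 and its opposing demethylases went both ways, with 3 of 15 genes higher and 3 lower, or 2 and 3 adjusted over the list alone. EZH2 (chromosome 7), the H3K27 methyltransferase, fell by 0.37 ± 0.0311 on the log2 scale, from 201 to 155 CPM, and newly made EZH2 RNA by 0.30 ± 0.0441. The median gene of chromosome 7 was at -0.392, close to EZH2. KDM6B, a demethylase of the same mark, rose by 0.47 ± 0.0627, LCOR by 0.20 ± 0.0298, and EED stood at -0.24 ± 0.0490. Of 71 Polycomb-marked developmental genes, 22 rose and 16 fell, or 23 and 16 adjusted over the list alone, and 22 rose and 5 fell once the 12 on chromosome 7 were left out. Without chromosome 7 camera made no call on this list (camera adjusted p = 0.483, and adjusted p = 0.85 with an estimated correlation). In newly made mRNA without chromosome 7, 5 of these genes rose and 5 fell. TBX15 rose by 0.89 ± 0.0698, HOXA9 (chromosome 7) was at -0.52 ± 0.0367 and EN2 (chromosome 7) at -3.16 ± 0.191. Of 18 Polycomb-silenced tumour suppressors, 9 rose and 4 fell, or 10 and 4 adjusted over the list alone, with SFRP1 at 3.34 ± 0.199 from only 0.583 CPM and CDKN2B at 0.84 ± 0.0921. Of 49 semaphorin and axon guidance genes, 14 rose and 15 fell, the same counts adjusted over the list alone. That list was drawn up knowing of SEMA5A and is not independent evidence for it. SEMA3E (chromosome 7) was at -1.11 ± 0.0420, SLIT3 at 0.72 ± 0.0411 and EFNA5 at 0.36 ± 0.0349.

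Lists of cell state and identity showed scattered changes, with counts adjusted over the list alone in parentheses. Heat shock proteins had 9 of 16 higher and 1 lower (10 and 1), led by DNAJB4 at 0.56 ± 0.0381 and HSPA8 at 0.24 ± 0.0282. Hypoxia genes had 8 of 24 higher and 6 lower (8 and 6), with LOX at 0.50 ± 0.0352 and SLC2A1 at 0.37 ± 0.0330. Renal tubule genes had 4 of 20 higher and 8 lower (4 and 8), with MME at 4.64 ± 0.179, CUBN at 2.06 ± 0.0690 and MET (chromosome 7) at -0.45 ± 0.0277. Epithelial markers had 5 of 19 higher and 6 lower (5 and 7), with TJP1 at 0.35 ± 0.0283 and KRT18 at -0.20 ± 0.0308. Replication-dependent histones had 9 of 41 higher and 16 lower (10 and 16), from HIST1H3I at -3.32 ± 0.221 to HIST1H2BC at 0.32 ± 0.0335. Interferon-stimulated genes had 4 of 39 higher and 9 lower (3 and 9), with IFI44L at -0.89 ± 0.106. Cell cycle genes had 7 of 43 higher and 9 lower (5 and 9), with CDC20 at 0.20 ± 0.0431 and MCM7 (chromosome 7) at -0.27 ± 0.0296. DNA repair genes had 4 of 35 higher and 13 lower (4 and 13), with ERCC1 at 0.46 ± 0.0338 and PMS2 (chromosome 7) at -0.50 ± 0.0505. Ribosomal protein genes had 8 of 60 higher and 9 lower (7 and 8), with RPS12 at 0.30 ± 0.0372 and RPLP2 at -0.25 ± 0.0366. C2H2 zinc finger and short-lived regulators had 2 of 38 higher and 9 lower (2 and 8), with ZNF92 (chromosome 7) at -0.71 ± 0.0507. snoRNA host genes on this table had 0 of 5 higher and 2 lower (0 and 2), with EIF4A2 at -0.20 ± 0.0290. Endothelial markers had 3 of 5 higher and 0 lower (3 and 0), with CDH5 at 3.16 ± 0.271, yet only from 0.325 to 2.93 CPM. Immune cell markers had 1 of 2 higher and 0 lower (1 and 0), CD4 at 0.96 ± 0.188.

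Of 15424 tested genes, edgeR called 3588 higher and 3378 lower in the knockout, of which 711 and 166 changed at least 2-fold. DESeq2 called 2272 and 2017, and limma on the authors' CPM, with both test and scale changed, called 2659 and 3694. In all RNA, camera called 5 of 23 lists with the preset correlation. With an estimated correlation it called 0, with 3 at an unadjusted p under 0.05.

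Genes of chromosome 7 were lower as a block. The median of 730 tested genes there was -0.392 in all RNA, a ratio of 0.762, with 64 genes called higher and 557 lower. Newly made RNA of 633 genes of chromosome 7 had a median of -0.39, with 34 higher and 408 lower. Medians of the other chromosomes with at least 20 tested genes ran from -0.0503 to 0.0599 in all RNA and from -0.0286 to 0.0591 in newly made RNA. Chromosome 7 supplied 16.5% of all genes called lower while holding 4.73% of those tested, and 27.1% of newly made RNAs called lower while holding 4.79%. SCIN, STRIP2, EZH2, HOXA9, MET and ASNS fell from within this chromosome.

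**Figure D1:**
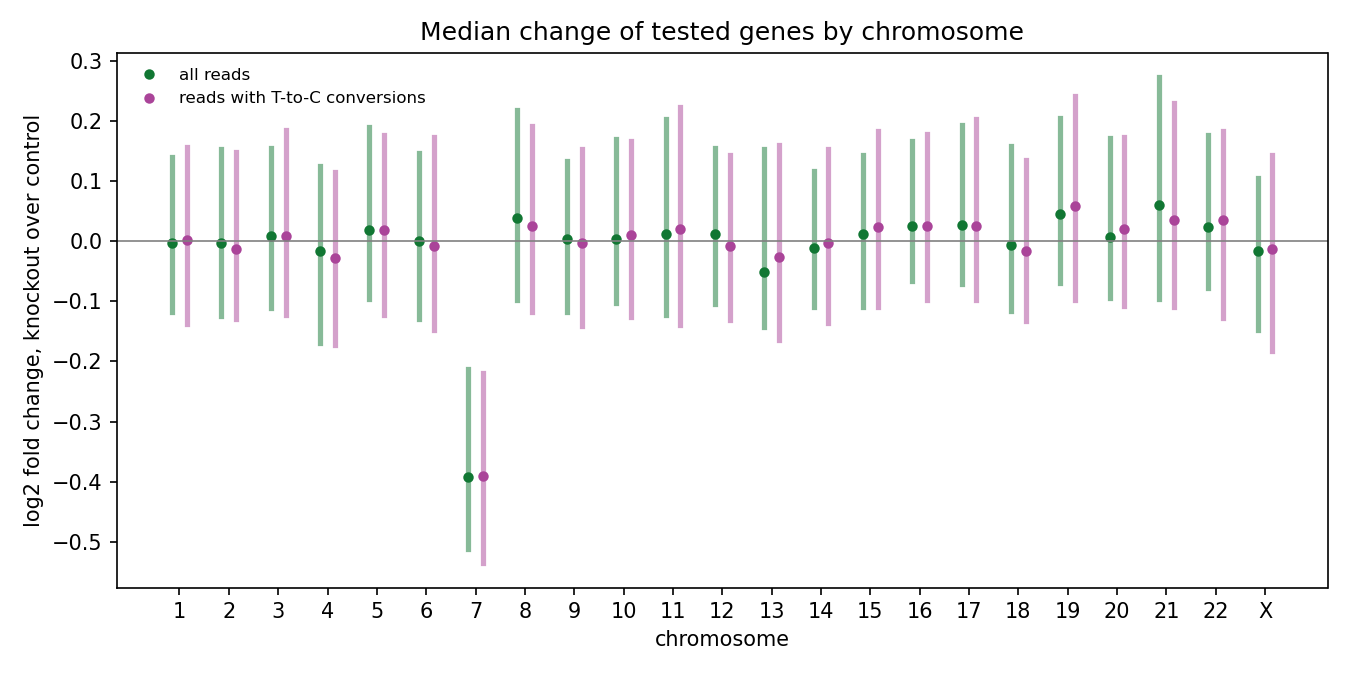
Median log2 change (knockout over control) of tested coding genes on each chromosome with at least 20 tested genes, for all reads and for reads with T-to-C conversions. Points are medians over genes, bars the middle 50% of genes, and chromosome 7 stands apart at -0.392 in all reads.

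Newly made mRNA asked which of these differences were present in RNA made during the label and not yet decayed. ZFPM2, a cofactor of GATA factors, rose among newly made transcripts from 6.85 ± 0.580 to 111 ± 6.53 CPM (SD, n = 2; log2 4.02 ± 0.110, edgeR adjusted p = 1.21e-27). CCSER1 rose by 4.00 ± 0.0990 on the log2 scale from 8.94 to 143, and SEMA5A 8.10-fold from 51.6 to 418. PTGIS was at 3.76 ± 0.0960, TEX14 at 3.71 ± 0.114, PCDH20 at 3.28 ± 0.128 and RP11-383H13.1 at 4.02 ± 0.134. CCND2 was 9.19-fold lower, at 23.9 against 220 in the controls. TM4SF4, a tetraspanin-like membrane protein, was 7.04-fold lower, SCIN 6.16-fold lower and SLC4A10, a bicarbonate transporter, 5.95-fold lower. ENTPD1 stood at -1.67 ± 0.124, GPM6A at -1.56 ± 0.0927, PALM2 at -1.55 ± 0.0856 and SLIT2 at -1.50 ± 0.0648.

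**Figure D2:**
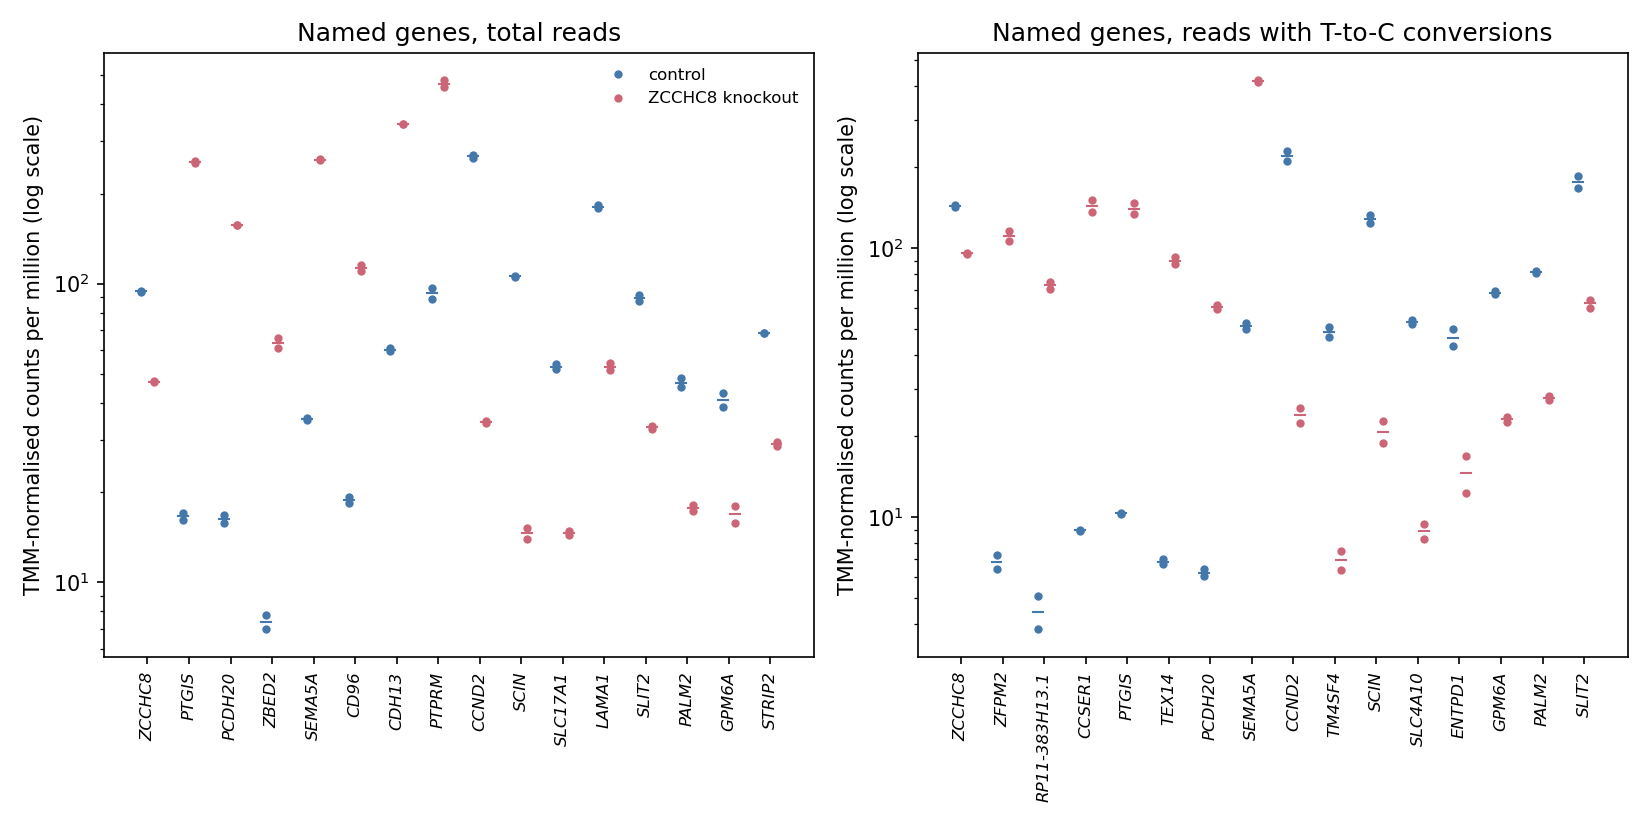
Level of each named gene in each library, in TMM-normalised CPM on a log scale, for all reads and for reads with T-to-C conversions. Points are the 2 control and 2 knockout libraries and short lines their means, as for PTGIS at 16.7 and 256 in all reads.

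The same 4 themes stood out among newly made mRNAs. Mesenchymal and matrix genes had 10 of 23 higher and 1 lower, or 12 and 2 adjusted over the list alone (camera adjusted p = 1.81e-18, and adjusted p = 0.16 with an estimated correlation), with FN1 at 1.74 ± 0.0431 and SPARC at 1.08 ± 0.0554. Immediate early genes had 19 of 35 higher and 3 lower, or 23 and 3 adjusted over the list alone (camera adjusted p = 4.82e-08, and adjusted p = 0.16 with an estimated correlation), with SGK1 at 1.09 ± 0.0630 and CTGF at 0.75 ± 0.0462. Of 26 p53 targets, 18 fell and 1 rose, or 19 and 1 adjusted over the list alone (camera adjusted p = 2.8e-08, and adjusted p = 0.16 with an estimated correlation), with CDKN1A at -0.74 ± 0.0493 and GDF15 at -0.85 ± 0.0642. The integrated stress and unfolded protein response had 12 of 29 lower and 0 higher in edgeR, or 13 and 1 adjusted over the list alone (camera adjusted p = 5.71e-06, and adjusted p = 0.597 with an estimated correlation), with DDIT4 at -1.09 ± 0.0570 and MTHFD2 at -0.53 ± 0.0523. Of the 13 mitochondrially encoded mRNAs, 0 were called in newly made RNA by edgeR, also adjusted over the list alone, and MT-CO3 was at -0.10 ± 0.0425 (camera adjusted p = 0.593). Without control replicate 2 that list reached adjusted p = 0.046. Calls in newly made RNA are relative to the typical newly made mRNA, which the authors' CPM places at -0.245. Converted reads over mitochondrially encoded mRNAs made up 12.04% of their reads in the controls and 11.69% in the knockouts. The lack of calls therefore does not show that their fall was absent from newly made RNA. The remaining lists were not called, with adjusted p from 0.347 to 0.95.

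Among 13215 tested newly made mRNAs, edgeR called 1675 higher and 1507 lower, 430 and 123 of them at least 2-fold. DESeq2 called 837 and 630, and limma on the authors' CPM, which puts the median newly made mRNA at -0.245, called 458 and 5857, so directions near that size hold only relative to the typical newly made mRNA.

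Across 13215 coding genes, changes in all and in newly made RNA had a Spearman rho of 0.758. It was 0.418 when the libraries were regrouped with 1 control and 1 knockout on each side. That lower value holds what shared reads and variation between libraries give together. In both kinds of RNA, 1473 genes were called higher and 1352 lower, while 24 were called in opposite directions. Over 18929 lncRNA loci rho was 0.739 against 0.413, with 2283 loci higher in both, 1752 lower in both and 53 opposite. Genes are not independent replicates, so no p is attached.

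The newly made share of all reads was lower in the knockout cells. Converted reads made up 23.8% ± 0.622 of gene reads in the controls and 20.6% ± 0.269 in the knockouts (SD, n = 2), 3.18 points apart. Over lncRNA loci the shares were 20.1% ± 0.580 and 17.7% ± 0.226, 2.41 points apart. Most of these loci overlap the span of a coding gene and can count its reads again, so the second difference is not independent of the first. Both differences exceeded the spread between replicates, though the exact two-sided permutation p is 0.333, the smallest that 2 against 2 libraries allow.

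Relative to the library's typical share, a few genes stood far apart; those named here were chosen after their values were seen. ZFPM2 rose from 2.56% and 2.84% newly made in the controls to 22.5% and 23.8% in the knockouts, a log2 change of 3.32 ± 0.0578 (limma adjusted p = 4.31e-05). CCSER1 rose from 2.38% and 2.43% to 17.3% and 18.8%, or 3.13 ± 0.0465. FLG was at 2.22 ± 0.0576 and TMEM107 at 1.33 ± 0.0597. SLC4A10 dropped from 11.6% in control replicate 1 to 1.94% and 2.23% in the knockouts, or -2.26 ± 0.0660. In all RNA, ZFPM2 and CCSER1 rose by only 0.70 ± 0.0369 and 0.87 ± 0.0328, and SLC4A10 stood at -0.30 ± 0.0336. Limma called 99 mRNAs with a higher and 31 with a lower share among 13277, and 177 and 41 of 19124 lncRNA loci. These counts rest on the variance trend, which was added after the data were seen, and without it limma called 2 and 0 mRNAs and 0 loci (1608 and 2314 features at an unadjusted p under 0.05). ZFPM2 and CCSER1 then had adjusted p = 0.0207, and FLG, TMEM107 and SLC4A10 were no longer called, at 0.0716. With the trend left in, the mRNA counts became 38 and 8 without control replicate 1, 47 and 10 without control replicate 2, 58 and 24 without knockout replicate 1, and 70 and 33 without knockout replicate 2. For lncRNA loci they became 137 and 15, 135 and 12, 9 and 2, and 13 and 3 in the same order, and 11 and 6 when only loci overlapping no coding gene were tested. All reads were counted over both strands at nested loci and converted reads mostly over one, so the share of a gene that overlaps another mixes the pair.

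Among lncRNA loci that overlap no coding gene and lie above the median level, XLOC_009228 rose and LINC01158 fell by the largest factors in the edgeR fit. XLOC_009228 (chromosome 11, 79848192 to 79868111) rose 14.8-fold, from 1.10 to 16.3 ± 0.699 CPM, a log2 change of 3.89 ± 0.116 (edgeR adjusted p = 3.06e-28). LINC00607 rose 9.28-fold from 1.68 to 15.7, LINC00704 7.48-fold and AC092684.1 7.67-fold. XLOC_l2_014012 (chromosome 7, 130566536 to 130567582) rose 12.8-fold from 5.62 to 72.1 and lies within the span of LINC-PINT. LINC01158 (ENSG00000233639; chromosome 2, 105424030 to 105469641) was 15.6-fold lower, at 1.02 ± 0.0369 (log2 -3.97 ± 0.120). CRNDE fell 2.27-fold, from 13.6 to 5.98, and CTC-503J8.6 stood at -1.18 ± 0.0853. RP3-438O4.4 was at 3.38 ± 0.105, RP11-200A1.1 at 2.65 ± 0.105 and LOC105376360 at 2.52 ± 0.0849. CHMP1B2P was at -0.92 ± 0.0806, CR627394 at -0.91 ± 0.0627 and RP11-711K1.8 at -0.91 ± 0.0697. The span of CHMP1B2P lies within that of CR627394, where reads can be counted for both. DPY19L2P2 and MYH16, both on chromosome 7, were at -0.86 ± 0.0578 and -0.85 ± 0.0891.

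Over all loci of the lncRNA table, most of the named loci overlapped coding genes, XLOC_009228 and LINC01158 being the exceptions. AC007193.6 rose 34.5-fold (5.11 ± 0.109), RP11-386I14.4 by 3.82 ± 0.135, NTM by 4.02 ± 0.138, and RP11-383H13.1 and LOC100132891, which overlap, by 3.95 ± 0.0903 and 3.85 ± 0.0936. RP11-13J10.1 was 19.9-fold lower (-4.32 ± 0.0846), TM4SF4 8.53-fold lower and HYDIN 4.24-fold lower. NTM, TM4SF4 and HYDIN carry the identifier of the gene they are paired with, so their changes are not evidence of a separate lncRNA. CCND2-AS1 and CCND2-AS2, which run across the start of CCND2, were at -2.50 ± 0.0817 and -2.36 ± 0.0972.

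Transcripts that start opposite a coding gene's promoter rose as a class. Of 519 bidirectional loci that overlap no coding gene, 359 rose and 20 fell, 288 rose at least 2-fold and 0 fell that far (edgeR). The median change was 1.24, or 2.36-fold. The risen loci named next are among the 8 largest rises of called loci above the median level of tested features. The smallest of those 8, RNU12, rose by only 0.56, so most of the 288 loci lay below that level. Together the 288 loci held 14019 reads in the controls and 54995 in the knockouts. CTD-2021J15.1 (chromosome 3, 98621268 to 98737406) rose by 1.63 ± 0.0368, from 41.1 ± 1.39 to 127 ± 2.19 CPM, and RAB30-AS1 rose 2.30-fold from 16.2 to 37.1. XLOC_006554, whose span overlaps KMT2E-AS1 on chromosome 7, rose by 1.81 ± 0.104, RP11-1094H24.4 by 1.00 ± 0.0760, RP11-692D12.1 by 0.92 ± 0.0883, KMT2E-AS1 by 0.80 ± 0.0629 and RNU12, the U12 RNA of the minor spliceosome, by 0.56 ± 0.0576. Against that current, RSBN1L-AS1 (chromosome 7) was at -0.73 ± 0.0705, CTD-2127H9.1 at -0.28 ± 0.0685, OSMR-AS1 at -0.28 ± 0.0684, FAM185BP (chromosome 7) at -0.27 ± 0.0615 and RN7SK, the 7SK RNA, at -0.17 ± 0.0327, from 7384 to 6554. CTD-2127H9.1 lies within the span of OSMR-AS1 and had almost the same reads. Loci that overlap in this way are counted separately in the class. Intergenic loci that overlap no coding gene had a median of only 0.0513, with 1115 of 4947 higher and 491 lower.

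**Figure D3:**
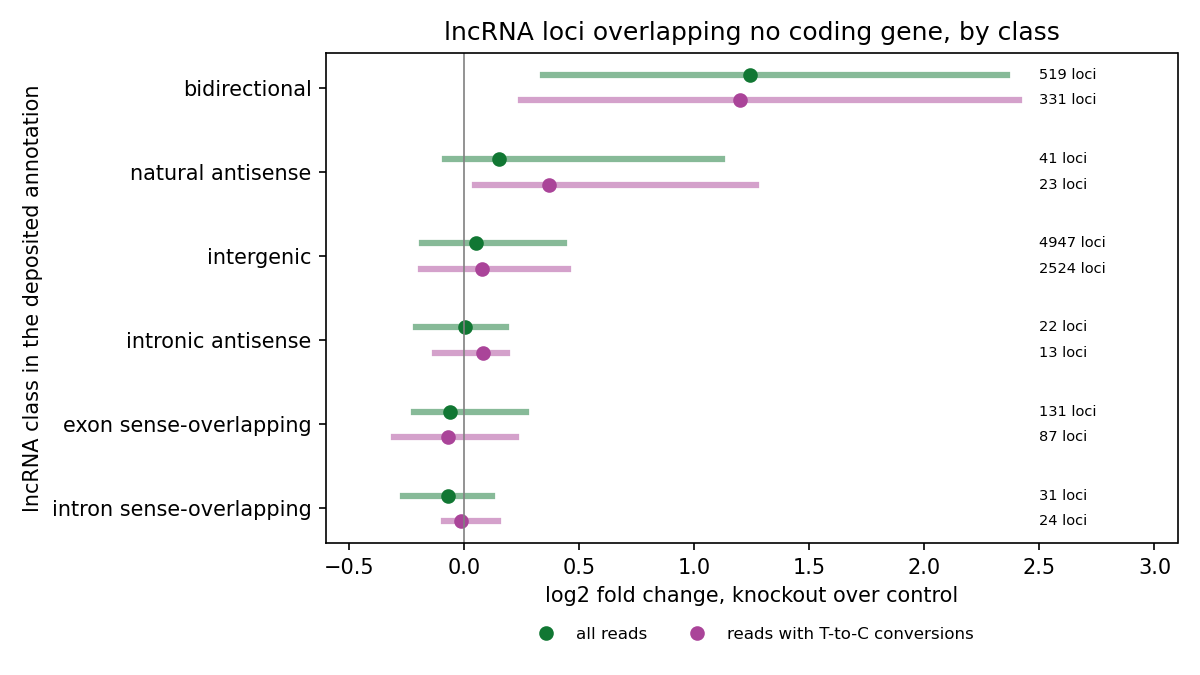
Log2 change (knockout over control) of lncRNA loci that overlap no coding gene, by class in the deposited annotation, for all reads and for reads with T-to-C conversions. Points are medians over the number of loci printed at the right and bars the middle 50% of loci, with bidirectional loci at 1.24 in all reads and a 2.30-fold rise in converted reads.

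Permutation within length and level strata found the bidirectional class above all other loci (600 loci, median rise 2.30-fold; mean of permuted differences 0.0509; p = 0.0001, the smallest that 10000 draws give; adjusted permutation p = 0.00023), and by 1.19 among loci that overlap no coding gene. Other classes differed far less. Natural antisense loci differed by 0.0313, intergenic loci by 0.0567, exon sense-overlapping loci by -0.0582 and intron sense-overlapping loci by -0.0178, with adjusted permutation p = 0.00023, 0.0007, 0.00023 and 0.032. Their means of permuted differences were -0.00244, 0.0386, -0.0217 and -0.00665, so the strata alone gave much of the intergenic value. Intronic antisense loci (0.0172) and loci longer than the median (-0.0403) were not called, with adjusted permutation p = 0.6 and 0.35. Among loci that overlap no coding gene, the intergenic difference was -0.568 because 519 of the loci it is set against were bidirectional, while the intergenic median itself stayed at 0.0513. The length difference turned there to 0.104 and was called, and natural antisense (0.0785) and intron sense-overlapping loci (-0.143) were no longer called. Without knockout replicate 1, or control replicate 2, the intron sense-overlapping difference was -0.0128 or -0.0112 and not called, and without knockout replicate 2 the intergenic difference was 0.0464 and not called. Without control replicate 2 the intronic antisense difference was 0.0340 and called, and the length difference was called without control replicate 1 (-0.0530) and without control replicate 2 (-0.0318).

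Among 40 tested loci of abundant nuclear lncRNAs, 21 rose and 8 fell, or 22 and 8 adjusted over the list alone (camera adjusted p = 0.000173, and adjusted p = 0.519 with an estimated correlation). That list holds 34 symbols, and the snoRNA host and DNA repair lists below hold 29 and 35. Some symbols therefore entered as several loci, which can share reads. LINC-PINT (chromosome 7) rose by 0.85 ± 0.0309 from 426 to 769 CPM, TERC, the telomerase RNA, by 0.99 ± 0.0653, LUCAT1 by 0.83 ± 0.0600 and PARTICL by 2.36 ± 0.179. C2H2 zinc finger and short-lived regulators had 2 of 35 loci higher and 11 lower, or 1 and 11 adjusted over the list alone (camera adjusted p = 0.0259, and adjusted p = 0.474 with an estimated correlation), and camera gave adjusted p = 0.128 without the members on chromosome 7. Of 33 snoRNA host loci, 10 rose and 8 fell, or 13 and 9 adjusted over the list alone, and camera made no call (adjusted p = 0.731). SNHG18 was at 2.05 ± 0.153, GAS5 at 0.48 ± 0.0360, SNHG3 at -0.40 ± 0.0312 and SNHG10 at -0.76 ± 0.0620. The other 4 called lists, namely mesenchymal, immediate early, p53 and stress response genes, entered this table through loci with the symbols of coding genes, and had adjusted p = 0.171, 0.209, 0.209 and 0.519 with an estimated correlation. DNA repair loci (4 of 45 higher and 16 lower, the same adjusted over the list alone) stood at adjusted p = 0.0672, and were called without control replicate 1 (0.041) and without knockout replicate 1 (0.042).

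Over 26938 tested lncRNA loci, edgeR called 5663 higher and 4825 lower, 2106 and 289 of them at least 2-fold, and DESeq2 called 3542 and 2632. Loci that overlap no coding gene numbered 5691, with 1516 higher and 553 lower, while of 21247 loci that overlap one, 4147 were higher and 4272 lower, with reads of the coding gene included; limma on the authors' CPM called 3893 and 4762 over all loci.

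Newly made lncRNAs were compared in the same way, as RNA made during the label and still present. XLOC_009228 rose 10.7-fold, from 2.65 ± 0.216 to 28.5 ± 0.639 CPM (SD, n = 2; log2 3.42 ± 0.181, edgeR adjusted p = 2.36e-14), and LINC00607 rose 7.19-fold from 3.39 to 24.6. RNU11 (chromosome 1, 28975112 to 28975245), the U11 RNA of the minor spliceosome, rose 6.39-fold from 6.31 to 40.4. LINC01158 was 15.7-fold lower, at 2.40 against 38.1 in the controls. XLOC_l2_006085 was at 2.74 ± 0.125, LINC01109 at 2.60 ± 0.159, AC092684.1 at 2.53 ± 0.149, XLOC_l2_014012 at 2.31 ± 0.105 and RP11-200A1.1 at 2.02 ± 0.176. LOC441204 and AC004540.5, which overlap on chromosome 7, were at -1.28 ± 0.154 and -0.84 ± 0.138, CRNDE at -0.93 ± 0.116, RP5-884C9.2 at -0.95 ± 0.161, CR627394 at -0.85 ± 0.104 and RP11-711K1.8 at -0.81 ± 0.104. Of loci that overlap coding genes, RP11-127H5.1 rose 35.5-fold from 0.816 to 29.7, and RP11-13J10.1 was 20.3-fold lower, HYDIN 5.21-fold lower and SKAP1 4.35-fold lower. RP11-127H5.1, HYDIN and SKAP1 carry the identifier of the gene they are paired with, so their changes are not evidence of a separate lncRNA.

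Newly made bidirectional transcripts rose as a class too. Of 331 loci that overlap no coding gene, 198 rose and 8 fell, 177 rose at least 2-fold and 1 fell that far. The median rise was 2.30-fold. The 8 largest rises of called loci above the median level of tested features ended at RPPH1, with only 0.24. Most of the 177 loci therefore lay below that level. CTD-2021J15.1 rose 3.11-fold from 93.7 to 292, RAB30-AS1 by 1.00 ± 0.0780 and RP11-692D12.1 by 0.80 ± 0.137, while RSBN1L-AS1 (chromosome 7) was at -0.80 ± 0.142. In the stratified permutation the class stood 1.12 above all other loci (382 loci; adjusted permutation p = 0.00017, at the smallest p that the draws give). Natural antisense loci differed by 0.0983, intronic antisense loci by 0.0898 and exon sense-overlapping loci by -0.0985, each with adjusted permutation p = 0.00017. The intergenic (0.0705) and intron sense-overlapping (-0.0058) differences were not called, with adjusted permutation p = 0.53 and 0.99. Loci longer than the median differed by -0.0610 (adjusted permutation p = 0.01), a call lost without control replicate 2 (-0.0531) and without knockout replicate 2 (-0.0628). Among loci that overlap no coding gene, the intergenic difference was -0.472, again set mostly against bidirectional loci and with an intergenic median of 0.077, the intronic antisense difference turned to -0.0232 over 13 loci and was not called (adjusted permutation p = 0.61), and length was not called (-0.0051).

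Of 32 newly made snoRNA host loci, 11 rose and 2 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.00996, and adjusted p = 0.66 with an estimated correlation). The list holds 29 symbols, so some entered as several loci, which can share reads. SNHG17 rose by 0.56 ± 0.0718, SNHG8 by 0.53 ± 0.111, GAS5 by 0.31 ± 0.0501 and SNHG18 by 1.86 ± 0.269. Abundant nuclear lncRNAs had 15 of 37 higher and 6 lower, or 15 and 7 adjusted over the list alone, without a camera call (adjusted p = 0.335), with MIAT at 1.63 ± 0.162 and LUCAT1 at 1.04 ± 0.141. C2H2 zinc finger and short-lived regulators had 0 higher and 9 lower of 35 loci in edgeR, the same adjusted over the list alone (camera adjusted p = 0.0398, and adjusted p = 0.494 with an estimated correlation). That call ended without the members on chromosome 7 (adjusted p = 0.118) and without knockout replicate 2 (adjusted p = 0.088).

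Among 18929 tested newly made lncRNA loci, edgeR called 2658 higher and 1969 lower, 1275 and 205 at least 2-fold, and 620 and 161 of the 3002 loci that overlap no coding gene, which became 549 and 254 when those loci were fitted alone. DESeq2 called 1351 and 786, and limma on the authors' CPM, which puts the median newly made locus at -0.223, called 667 and 6355.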

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

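Fits without chromosome 7, fits on loci that overlap no coding gene, and the variance trend in the share test, with the comparison to fits without it, were chosen after the data were seen; the other alternatives were planned. The cause of a change was not tested unless the setting itself shows it, as with fewer libraries or a stricter rule.

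Named genes kept their call status in 1374 comparisons with an alternative, and in 40, over 11 features, the direction held while the call ended. Gene lists kept theirs in 582, lost it in 24 and gained it in 3. No named gene and no called list reversed its direction under the alternatives run on it, while lists that were not called could change side, as Polycomb-marked developmental genes did without chromosome 7.

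DESeq2 called 2272 genes higher and 2017 lower, 837 and 630 newly made mRNAs, 3542 and 2632 lncRNA loci, and 1351 and 786 newly made loci; the cause was not tested. A 2-fold minimum left 711 and 166, 430 and 123, 2106 and 289, and 1275 and 205 in the same order. Limma on the authors' CPM called 458 newly made mRNAs higher and 5857 lower, and 667 and 6355 newly made loci; both the test and the scale differ there, and the cause was not tested. Without a filter 1291 newly made loci were lower. Only loci overlapping no coding gene gave 1324 higher and 757 lower in all reads and 549 and 254 in converted reads. In the fit of all loci the same loci gave 1516 and 553, and 620 and 161. TMM was fitted on these loci alone in the restricted setting, which tends to remove a rise common to them. Their medians in the fit of all loci were 0.0725 in all reads and 0.104 in converted reads. How much of the difference came from this scaling was not tested.

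Leaving out each library in turn gave 3037 to 3114 genes higher and 2744 to 3059 lower, 1315 to 1418 and 1155 to 1222 newly made mRNAs, 4742 to 4978 and 3747 to 4174 loci, and 2164 to 2282 and 1571 to 1659 newly made loci. A lone library was taken to vary like the other group. With an estimated correlation camera called 0 lists in the tables of all reads over genes, newly made mRNA, all reads over lncRNA loci and newly made lncRNA loci, against 5, 4, 6 and 6 with the preset one, and 3 had an unadjusted p under 0.05 in each.

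The share test depended most on its settings. At least 50 reads gave 62 mRNAs with a lower share, and 285 loci higher and 99 lower. No centring gave 153 and 4533 mRNAs and 297 and 2973 loci, since the lower share of the whole library then enters each feature. Without a variance trend limma called 2 mRNAs higher and 0 lower and 0 loci either way (1608 and 2314 features at an unadjusted p under 0.05), and the replicate block gave 16 loci lower. Only loci overlapping no coding gene gave 11 and 6. Leaving out each library gave 38 to 70 mRNAs higher and 8 to 33 lower, and 9 to 137 loci higher and 2 to 15 lower. The 38 and 8 mRNAs came without control replicate 1, against 47 and 10 without control replicate 2, 58 and 24 without knockout replicate 1, and 70 and 33 without knockout replicate 2. In the same order the loci were 137 and 15, 135 and 12, 9 and 2, and 13 and 3.

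Only loci overlapping no coding gene gave intergenic differences of -0.568 in all reads and -0.472 in converted reads, where intergenic loci are set mostly against bidirectional ones and their own medians stayed at 0.0513 and 0.077. It turned the length difference in all reads to 0.104 and the intronic antisense difference in converted reads to -0.0232, the latter no longer called over 13 loci (adjusted p = 0.61). There the natural antisense (0.0785) and intron sense-overlapping (-0.143) differences in all reads and the length difference in converted reads (-0.0051) were not called. Leaving out each library gave, in all reads, intron sense-overlapping differences of -0.0219 to -0.0112 (not called without knockout replicate 1, -0.0128, or control replicate 2, -0.0112) and intergenic ones of 0.0464 to 0.0661 (not called without knockout replicate 2, 0.0464). Length ran from -0.0530 to -0.0318, called without control replicate 1 (-0.0530) and control replicate 2 (-0.0318), and intronic antisense from 0.0127 to 0.0340, called without control replicate 2 (0.0340). In converted reads length ran from -0.0896 to -0.0531 and was not called without control replicate 2 (-0.0531) or knockout replicate 2 (-0.0628). The bidirectional difference kept its call in every setting, at 1.17 to 1.22 in all reads and 1.08 to 1.17 in converted reads over the libraries left out.

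Alternatives planned for motif loop length and the definition of U-rich sequence were not run for want of sequence, and those for normalized values (pseudocount, quantile normalization, limma without a trend) were not run because counts were used. Small changes can be missed: on simulated data 51% of 1.2-fold changes were recovered in all reads over genes, and 19.1% in newly made lncRNA loci. Whether depth or the number of libraries set that limit was not tested.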

Other observations

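The edgeR fits were planned, while the variance trend in the share test, the Gene Ontology tests, the tests of explanations and the genes named in this part were chosen after the results were seen.

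Some small nuclear and nucleolar RNA loci, picked for their size of change, rose more in converted reads than in all reads, and others did not. RNU11 rose 6.39-fold among newly made lncRNAs, from 6.31 to 40.4 CPM, and 2.05-fold in all reads, with edgeR adjusted p = 1.01e-14 and 1.91e-18. RNU12, also of the minor spliceosome, rose 5.04-fold and 1.48-fold. SNORD3A, the U3 snoRNA that acts in ribosomal RNA processing, rose by 0.92 ± 0.0532 from 98.8 to 187 in converted reads and by 0.19 ± 0.0300 from 576 to 657 in all reads. The newly made share of SNORD3A went from 3.43% and 3.52% to 5.02% and 4.95%, that of RNU12 from 5.05% and 5.31% to 15.7% and 14.9%, and that of RNU11 from 9.96% and 10.4% to 28.6% and 26.4%. Limma called the share of all 3 loci, but none without the variance trend (adjusted p = 0.128 for SNORD3A and 0.0997 for RNU11 and RNU12), and for RNU12 and RNU11 the call ended without knockout replicate 1 (adjusted p = 0.0606 and 0.0643) and without knockout replicate 2 (adjusted p = 0.0615 and 0.0725). SNORA76 was at 0.75 ± 0.229 in converted reads and 0.06 ± 0.0820 in all reads, while SCARNA2 was at 0.02 ± 0.231 and -0.27 ± 0.0414. SNORD3D was at 2.41 ± 0.449 and 2.78 ± 0.286, SCARNA15 at 0.76 ± 0.246 and 0.78 ± 0.163, SCARNA9L at 0.69 ± 0.434 and 0.72 ± 0.147, and SNORD116-20 at -0.22 ± 0.356 and -0.04 ± 0.0793. No test was run on small RNA loci as a group. Reads over TMEM107, a gene of the ciliary transition zone, rose 4.62-fold in converted reads and 1.84-fold in all reads. Whether they came from its mRNA or from another RNA within its span was not tested.

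Some lncRNAs moved with a coding neighbour. POU3F3, a POU-domain transcription factor, fell together with LINC01158 beside it, at -4.38 ± 0.109 in all RNA (864 and 777 reads in the controls, 39 and 46 in the knockouts) and -4.01 ± 0.256 in newly made mRNA. RP11-13J10.1 overlaps the span of POU3F3, where reads can be counted for both, so its fall is not separate evidence. IRX5, next to CRNDE, was at -3.18 ± 0.314 on few reads (65 and 71 against 11 and 5), while IRX3, farther along the same cluster, was at 0.25 ± 0.139. MYC was at 0.27 ± 0.0318.

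Of the 711 genes at least 2-fold higher, 465 carried a Gene Ontology term of biological process. The terms with the smallest p were female pregnancy (10 of 47 tested genes), flavonoid glucuronidation (5 of 10, 12.4 times the background share) and cellular glucuronidation (5 of 11, 11.2 times), each with hypergeometric adjusted p = 0.012. That test takes genes as independent. Whether the glucuronidation genes overlap and share reads, or are the same genes in both terms, was not checked. Cell adhesion held 25 of its 257 tested genes, 2.40 times the background share (adjusted p = 0.012), ion transmembrane transport 19 of 166 (2.83 times) and extracellular matrix disassembly 11 of 76 (3.58 times). In total 17 of 1297 terms passed, and 0 of 1297 for genes at least 2-fold lower, where 36 terms had an unadjusted p under 0.05. Over called genes of any size, extracellular matrix organization held 75 of 186 higher (adjusted p = 4.9e-05) and, with chromosome 7 left out, cilium assembly held 39 of 98 lower (adjusted p = 0.0038).

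A few loci had one library far apart in converted reads alone. CTD-2033D15.1 had 6 and 477 converted reads in the controls beside 2504 and 2363 reads in all, RP11-664D7.4 had 13 and 111 and AK126278 92 and 16. In the knockouts RP11-265N6.3 had 199 and 22 and the KIF22 locus 153 and 35.

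Bidirectional lncRNAs rose by a median of 1.24. Reads spilling over from the paired coding gene were argued against, since loci whose partner moved by under 0.1 still rose by 1.14 (95% bootstrap interval 0.72 to 1.53, 155 loci). Genomic DNA as the source of all the added reads was argued against. Of the reads added at 288 loci, 30.8% carried conversions (28.1 to 33.1), above the 20.79% of coding reads in knockout replicate 2, the higher knockout. A smaller part of genomic DNA was not excluded. Over the 175 risen bidirectional loci with a tested share, the newly made share was 36.4% in the controls and 34.6% in the knockouts. A low level was argued against, since the class stood 1.12 (0.914 to 1.26) above intergenic loci of like level. An effect of ZCCHC8 knockout on these transcripts may remain, as a hypothesis found and tested on the same 4 libraries.

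The fall of chromosome 7 genes ran along the whole chromosome. A few strongly changed genes were argued against, since the highest of 32 windows of 10 Mb in both tables had a median of -0.307, and gene length or level was argued against by a difference of -0.403 (-0.419 to -0.386) from matched genes elsewhere. A lower dosage of chromosome 7 in the knockout cells is a candidate explanation, since all and newly made RNA fell alike, 0.0091 apart (-0.0001 to 0.02, 633 genes), at ratios of 0.758 and 0.763. No DNA was measured, and a dosage difference between the groups and an effect of ZCCHC8 on this chromosome were not separated by this design.

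Slower decay on the time scale of the label would lower the newly made share of lncRNAs that rose at least 2-fold. The labelling time is not given, so decay much faster than the label would escape this test. The loci were also picked by their rise in all reads, by which the share is divided. Centred on each library's median, the share of bidirectional loci changed by a median of 0.053 on the log2 scale (-0.018 to 0.12, 175 loci) and that of intergenic loci by -0.067 (-0.15 to -0.0012, 298 loci). Without centring, which removes a fall of 0.21 common to the lncRNA loci, the changes were -0.16 (-0.23 to -0.093) and -0.28 (-0.36 to -0.21). Slower decay and more synthesis cannot be told apart for either class, since it is not settled whether that common fall came from labelling or from decay. The share over mitochondrially encoded mRNAs fell less, from 12.04% to 11.69%, than that over all genes, from 23.8% to 20.6%. Whether those mRNAs take up the label as other RNAs do was not tested, so this does not decide the question.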
